A study of Staphylococcus epidermidis with 6 samples.

How the data were processed

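Total RNA from Staphylococcus epidermidis biofilms was sequenced in 6 libraries, 3 labelled dormant and 3 labelled non-dormant. The labels do not say whether the libraries of a group came from separate cultures, so p-values of the comparison of groups measure only the spread between these libraries, which may be technical. Per the labels' protocols, RNA was purified on columns, treated with DNase, precipitated with acid phenol and chloroform, depleted of rRNA with magnetic probes for Gram-positive bacteria, and made into libraries with the Illumina TruSeq RNA kit, version 2, which does not mark the strand. Reads from a gene and from a transcript antisense to it therefore cannot be told apart. Growth conditions and the treatment behind the 2 groups were not given in the labels used here.

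The deposited files hold 1 RPKM value per transcript and library, per the file headers; RPKM, computed by the authors, is a read number divided by the length of the transcript and by the read total of the library. Bowtie 0.12.2 is named in the submitters' processing notes. The read counter, the genome build, the annotation and any filter were not given in the sources used here. Transcripts are named by 737 gene symbols, 1291 locus tags that begin with SERP and 3 other identifiers. The files do not pair the locus tags with names, and the reference table used here, of the assembly ASM609437v1 of strain ATCC 14990, does not carry these tags; 424 of the symbols were found in it. It was used only for lengths and gene order, and no coordinates are given. Together the files list 2031 transcripts, with no value at 0 and a lowest value of 1.80 RPKM. The 2 files of a replicate number list the same transcripts in the same order, and 1690 transcripts are listed in all 6 files. With no value at 0, a transcript without reads in any 1 library cannot be among these 1690. Genes silent in a group were therefore outside the comparison.

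RPKM values of a library step in multiples of what 1 read is worth, so whole reads could be recovered. A read total per library was found that turned 93.5% to 94.7% of the values of transcripts with a reference length into whole reads within 0.02 of a read. Of 415 recovered transcript lengths that could be compared, 91.8% equalled the reference length. The recovered totals were 276426, 217557 and 189908 reads for dormant replicates 1, 2 and 3, and 172030, 170656 and 205881 reads for non-dormant replicates 1, 2 and 3. The median transcript had 10 to 89 reads in a library, so counting error is large for weak transcripts. Intervals of shares are 95% Wilson intervals on recovered reads, and they cover counting error only, since PCR copies are not independent molecules. No pair of libraries agreed within sampling noise: the lowest chi-square per degree of freedom, over transcripts, was 5.25.

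The tests had been planned before the data were examined for counts. Because the files hold RPKM, the planned replacement was used: limma-trend (limma 3.58.1 in R 4.3.3) on log2(RPKM + 1), for the transcripts listed in all 6 files with a mean of at least 1 RPKM, a filter that removed 0. The model had the group as its only term. Benjamini-Hochberg adjusted p-values were called at 0.05. Fold changes are dormant over non-dormant on the log2(RPKM + 1) scale, which understates the change of low genes. The number of replicates is 3 per group throughout, and errors are SDs unless called SE. Of 29 gene lists fixed by symbol before the data were examined, 26 had at least 4 members and were tested with camera at a preset inter-gene correlation of 0.01, with adjustment over the lists; camera with an estimated correlation and fry were the alternatives. The files give no product names, so lists hold genes with symbols only.

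The rule for named genes was fixed before the data were examined. Had 10 or more genes passed, the largest changes were to be named. Fewer did, so the 8 genes of smallest unadjusted p in each direction were taken, given as values and not as calls, among genes with a symbol, a mean of at least 20 RPKM (the rule was written for CPM) and the same direction in all 3 same-numbered pairs. The rule adds the 3 members of smallest p of each list past the set test and 1 member of each other tested list. Of the locus tags, the 2 of smallest p in each direction are given; names were not available for them. Genes with numbered copies, such as gapA-2, arcB-2 and mqo-4, may share reads with their copies, since how the authors treated such reads was not given in the sources used here. Single values per library were compared with exact two-sided permutation tests, whose smallest possible p with 3 against 3 is 0.1.

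The alternatives set before the data were examined were median-of-ratios and upper-quartile scaling, a mean of at least 50 RPKM, a pseudocount of 0.1, removal of rRNA genes, the replicate number as a block, a minimum change of 2-fold, each library left out in turn, and the alternative set tests. Alternatives added after seeing the data were quantile normalization, a covariate for each library's 5th percentile of RPKM, subtraction of a background level for genes with a mean of at least 1000 RPKM, limma-voom on the recovered reads, the 3 libraries with the raised background left out, and transcripts listed for at least 2 replicate numbers. The planned count-based tests were not run, since the files hold no counts. Scaling by library totals alone is what RPKM already is, and dropping the filter left the same transcripts.

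The procedure was tested on simulated data for this comparison, with 1689 genes. With counting error only, 71% of 2-fold and 96% of 4-fold changed genes were recovered, with 8 false calls. With the residual spread of the real libraries added, 0% of either were recovered. A list shifted on purpose was called in both, and 0 other lists were. The simulated spread was independent between genes, so this cannot show how the set test fares where genes move together. Other splits of the real libraries into 3 and 3 called 4 to 10 lists. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.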

Results

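Transcript levels were measured by RNA sequencing in biofilms of Staphylococcus epidermidis, a bacterium of human skin that also grows as surface-attached communities on implanted medical devices. The 6 libraries formed 2 groups of 3, from biofilms labelled dormant and non-dormant, and the comparison asks which transcripts differ between these 2 groups. Dormant cells are viable cells of low metabolic activity. Values are the authors' RPKM for the 1690 transcripts listed in all 6 files. Recovered read totals ranged from 170656 in non-dormant replicate 2 to 276426 in dormant replicate 1, and all values below rest on 3 libraries per group.

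The libraries differed in the level of their weakest transcripts in a way that did not follow the groups. The 5th percentile of RPKM was 144, 129 and 99.8 in dormant replicate 1, non-dormant replicate 1 and non-dormant replicate 3, against 12.3, 11.8 and 8.48 in dormant replicate 2, dormant replicate 3 and non-dormant replicate 2. The former 3 are called the high-background libraries below. This difference was the first principal component, with 87.6% of the variance of log2 values. Ribosomal RNA took from 0.0232% (95% Wilson interval 0.0173% to 0.0311%) of the reads in dormant replicate 3 to 2.48% (2.41% to 2.54%) in dormant replicate 2, and the group means were 0.963% ± 1.32 and 0.235% ± 0.117 in dormant and non-dormant libraries (exact permutation test, two-sided, p = 0.6). The 10 most abundant transcripts took from 14.7% (14.5% to 14.8%) of the reads in dormant replicate 1 to 50.4% (50.2% to 50.6%) in non-dormant replicate 2, with means of 28.9% ± 12.5 and 31.0% ± 17.4 (exact permutation test, two-sided, p = 0.9).

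**Figure D1:**
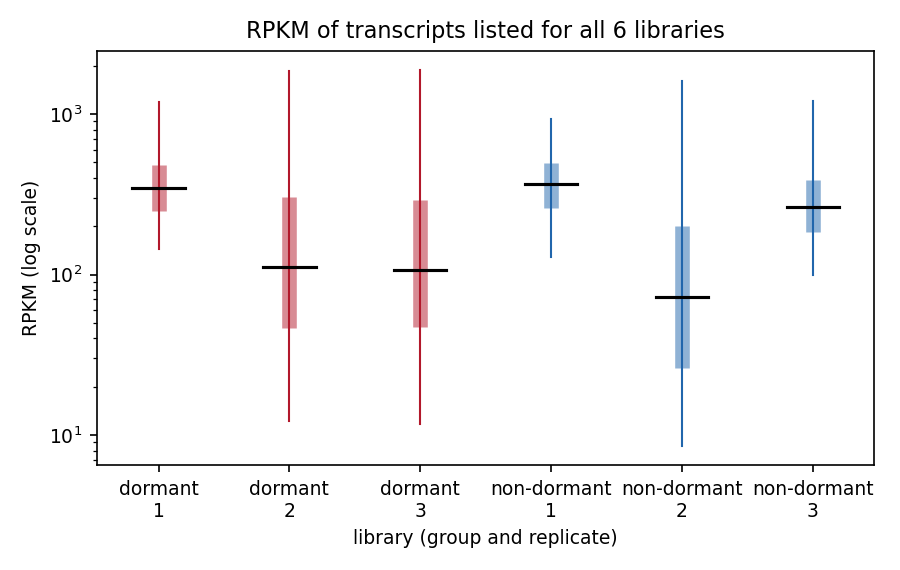
RPKM (log axis) of the transcripts listed in all 6 files, by library. Thin lines span the 5th to the 95th percentile, thick bars the quartiles, and black lines mark medians, which lie at 347, 364 and 263 RPKM in the 3 high-background libraries and at 112, 107 and 72.1 RPKM in the others.

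The 8 genes with symbols of smallest p above the non-dormant level were ylmF, recA, gapA-2, hemA, ccpA, mqo-4, pflA and ribD, which were 2.08-fold to 2.91-fold higher in the dormant biofilms. Transcripts of recA, the recombinase of DNA repair and of the SOS response, averaged 4789 ± 1661 RPKM in dormant and 1654 ± 342 RPKM in non-dormant biofilms. Those of gapA-2, a glyceraldehyde-3-phosphate dehydrogenase, averaged 1000.2 ± 298 against 339.6 ± 92.8 RPKM, and those of ccpA, the regulator of carbon catabolite control, 807 ± 179 against 322 ± 37.0 RPKM. The division gene ylmF stood at 971 ± 220 against 346 ± 28.5 RPKM, and hemA, for the first enzyme of haem synthesis, at 964 ± 177 against 414 ± 19.3 RPKM. For mqo-4, a malate:quinone oxidoreductase, for pflA, the activator of pyruvate formate-lyase, and for ribD of riboflavin synthesis the folds were 2.16, 2.08 and 2.15. Some of these values lay near the background. The 300 genes weakest outside the high-background libraries had quartiles of 244 and 432 RPKM in non-dormant replicate 1. There ccpA, ribD, ylmF and hemA lay within these quartiles, at 323, 351, 372 and 427 RPKM. Above them lay gapA-2 at 436 RPKM, pflA at 623 RPKM, recA at 1268 RPKM and mqo-4 at 1288 RPKM.

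Among the genes below the non-dormant level, ctsR, the repressor of the clp heat shock genes, averaged 2280 ± 562 RPKM in dormant and 6329 ± 3038 RPKM in non-dormant biofilms, 2.62-fold lower. The urease subunit genes ureA, ureB and ureC were 2.79-fold, 2.81-fold and 1.93-fold lower, with ureB at 219.8 ± 137 against 556 ± 84.5 RPKM. Reads were few for ureA (13 and 5) and ureB (12 and 11) in dormant replicates 2 and 3, against 177 and 90 for ureC. In dormant replicate 1 ureA stood at 263 RPKM, near the background. There the 300 genes weakest outside the high-background libraries had a median of 283 RPKM. The pyrophosphatase gene ppaC stood at 444 ± 50.5 against 862 ± 116 RPKM. The ribosomal protein genes rpsH and rpsQ and the galactose-6-phosphate isomerase gene lacB were 2.36-fold, 2.08-fold and 1.95-fold lower, with 11, 10 and 18 reads in dormant replicate 3. Of transcripts named by locus tag only, SERP2115 and SERP2165 were 2.51-fold and 2.38-fold higher, and SERP0163 and SERP0224 were 2.49-fold and 3.04-fold lower.

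None of these differences passed the test over all genes. With limma-trend, 0 genes were higher and 0 lower at an adjusted p below 0.05, the smallest adjusted p was 0.218, and 76 genes were higher and 14 lower at an unadjusted p below 0.05; limma-voom on the recovered reads also called 0. Adjusted over the list alone, mqo-4, gapA-2, pflA, pflB, recA and ccpA were higher and ctsR lower, against 0 of them over all genes tested. Without dormant replicate 1, 41 genes were higher and 4 lower, and without non-dormant replicate 1, 5 were higher and 6 lower. In both fits limma pooled 1 common spread over all genes, with a median of 5070 degrees of freedom against 12.9 in the main fit. These calls therefore cannot be assigned to the library left out. Leaving out the 3 high-background libraries leaves non-dormant replicate 2 alone in its group and assumes it varies like the dormant libraries. The median log2 difference of all genes was then 0.61, against -0.17 in the main fit. A count of calls there would include this shift and is not given.

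**Figure D2:**
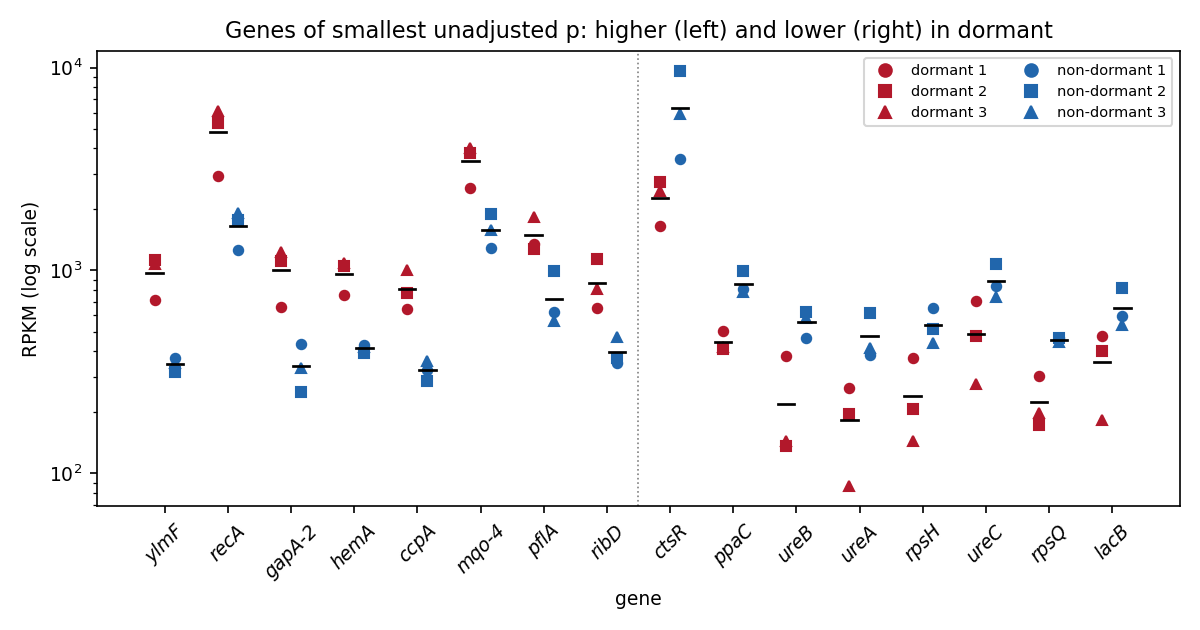
RPKM (log axis) of the 8 genes of smallest unadjusted p that were higher (left of the dotted line) and the 8 that were lower (right) in dormant biofilms. Each symbol is 1 library, red for dormant and blue for non-dormant, and black lines mark group means; ctsR, for example, averaged 2280 RPKM in dormant and 6329 RPKM in non-dormant biofilms.

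Genes of the tricarboxylic acid cycle lay higher relative to the other genes in the dormant biofilms by camera at a preset correlation, a call that was lost when the correlation was estimated. Of 15 members, 13 lay above 0 and the median log2 difference was 0.49, against -0.17 for all genes (camera, adjusted p = 2.79e-06; adjusted p = 0.525 with an estimated correlation). Besides mqo-4, at 3457 ± 790 against 1590 ± 309 RPKM, the members of smallest p were sucA and sucB, both for subunits of 2-oxoglutarate dehydrogenase, which were 1.98-fold and 2.08-fold higher. The aerobic respiratory chain lay higher by the same test, also lost with an estimated correlation, with 7 of 8 members above 0 and a median of 0.68 (camera, adjusted p = 0.000526; adjusted p = 0.340 with an estimated correlation). Its members ctaB, for haem O synthesis, and qoxA and qoxC, for subunits of the quinol oxidase, were 2.10-fold, 1.57-fold and 1.70-fold higher. The fermentation and pyruvate overflow genes had 6 of 7 members above 0 and a median of 0.38 (camera, adjusted p = 0.00919; adjusted p = 0.656 with an estimated correlation), led by pflA and by pflB, for pyruvate formate-lyase, at 1579 ± 257 against 906 ± 292 RPKM. In that list pta, for phosphate acetyltransferase, was 1.31-fold higher. With the high-background libraries left out, which leaves non-dormant replicate 2 alone in its group, the medians were 0.84 for the cycle, 0.83 for the respiratory chain and 0.37 for fermentation, against 0.61 for all genes (adjusted p = 0.00756, 0.205 and 0.991). The fermentation call was also lost without non-dormant replicate 1 (adjusted p = 0.407) and without dormant replicate 3 (0.178).

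Ribosomal protein genes lay lower relative to the other genes by camera at the preset correlation but not at an estimated one. Of 48 members, 36 lay below 0 and the median was -0.38 (camera, adjusted p = 0.00402; adjusted p = 0.656 with an estimated correlation). Not every member shared the direction: rpsB averaged 2110 ± 651 RPKM in dormant and 1121 ± 368 RPKM in non-dormant biofilms, while rpsH averaged 241 ± 117 against 536 ± 110 RPKM. With the replicate number as a block the adjusted p (camera) was 0.0722, and without dormant replicate 1 it was 0.871. Without non-dormant replicate 2 the list pointed the other way relative to the other genes (camera, adjusted p = 0.570). The median of all genes was -0.60 and -0.78 in these latter fits, against -0.17 in the main fit. With the high-background libraries left out and non-dormant replicate 2 alone in its group, the list median was -0.39, against 0.61 for all genes.

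Chaperone and Clp protease genes lay lower relative to the other genes at the preset correlation but not at an estimated one, with 10 of 14 members below 0 and a median of -0.29 (camera, adjusted p = 0.0187; adjusted p = 0.614 with an estimated correlation). Apart from ctsR, the members of smallest p were clpB, for a disaggregase, at 6637 ± 1598 against 15242 ± 9059 RPKM, and groES, for the co-chaperonin, at 401 ± 177 against 722 ± 301 RPKM. Both lay lower in the dormant library of all 3 same-numbered pairs. Reads were few for groES, with 20, 37 and 19 in dormant and 20, 49 and 44 in non-dormant replicates 1, 2 and 3. Its 254 RPKM in dormant replicate 1 lay below the median of 283 RPKM of the 300 genes weakest outside the high-background libraries. Over the alternatives the log2 difference of clpB ran from -1.76 to -0.62. The direction of the list relative to the other genes turned without non-dormant replicate 2 (camera, adjusted p = 0.823), and the call was lost without dormant replicate 1 (0.535). The median log2 difference of all genes was -0.78 and -0.60 in these fits, against -0.17 in the main fit, so the other genes moved too. With the high-background libraries left out and non-dormant replicate 2 alone in its group, the list median was -0.46, against 0.61 for all genes.

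The list of the arginine deiminase pathway and urease lay narrowly past the threshold on the lower side at the preset correlation, with 10 of 12 members below 0 and a median of -0.35 (camera, adjusted p = 0.0496; adjusted p = 0.794 with an estimated correlation), but its parts diverged. The urease genes and arcA, arcB-1 and arcD lay below 0, whereas arcB-2, an ornithine carbamoyltransferase gene of arginine breakdown, averaged 7125 ± 3573 RPKM in dormant and 2655 ± 1276 RPKM in non-dormant biofilms, 2.73-fold higher. Another member, arcC, for carbamate kinase, chosen after its values were seen, had a log2 difference of 1.47 ± 0.54 (SE) and was higher in the dormant library of all 3 pairs. The call was lost with the replicate number as a block (adjusted p = 0.695), without dormant replicate 1 (0.353), without non-dormant replicate 3 (0.0707) and without non-dormant replicate 2 (0.998, in the other direction), and the adjusted p was 0.000349 with the high-background libraries left out and non-dormant replicate 2 alone in its group.

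**Figure D3:**
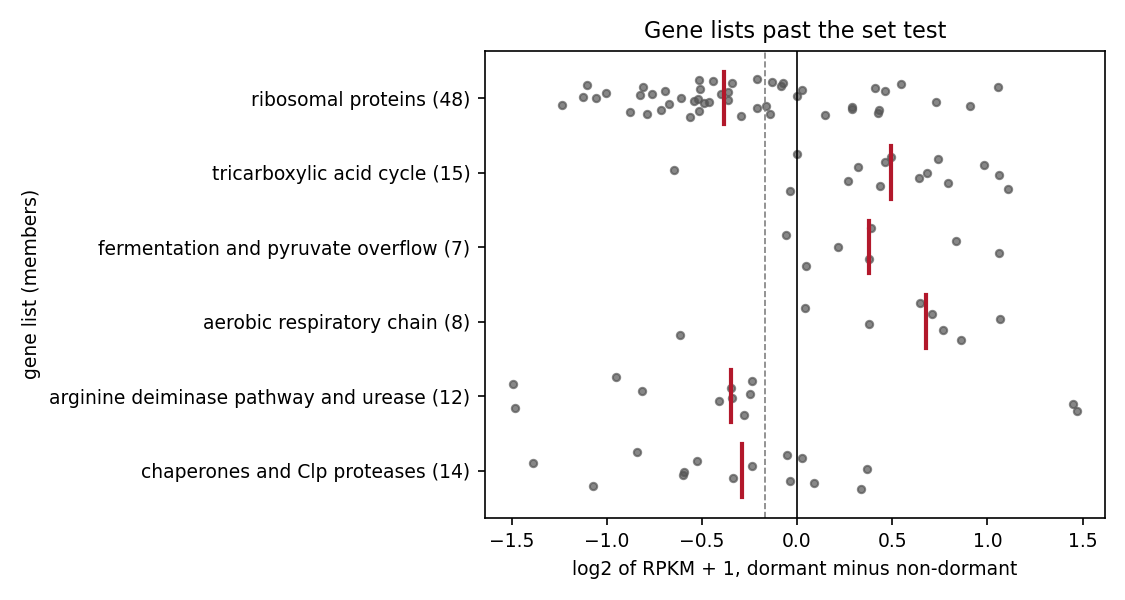
Log2 difference (RPKM + 1, dormant minus non-dormant) of each member of the 6 gene lists past the set test, with the number of members in brackets. Grey points are genes, red bars list medians, and the dashed line the median of all genes at -0.17; list medians run from -0.38 for ribosomal proteins to 0.68 for the aerobic respiratory chain.

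With median-of-ratios scaling, only the tricarboxylic acid cycle of these 6 lists passed (camera, adjusted p = 0.0163). With fry, which tests a list against no change rather than against the other genes, none did (adjusted p from 0.425 to 0.473). The other 20 lists did not pass, with adjusted p from 0.0557 to 0.981 (camera). Closest was purine biosynthesis, with 14 of 14 members below 0, a median of -0.87 and an adjusted p of 0.0557, and its member of smallest p, guaB, stood at 732 ± 174 against 870 ± 104 RPKM. Between the replicate 2 libraries, both of low background, the median log2 difference of this list was only -0.02 relative to that of all genes. Biofilm matrix and surface protein genes had 7 of 9 members below 0 (adjusted p = 0.290), with the surface protein gene sdrH at 564 ± 372 against 758 ± 285 RPKM. Between the replicate 2 libraries the median of this list was 0.005 relative to that of all genes, and sdrH stood at 993 RPKM in both libraries of replicate 1. Of the SigB operon and its reporters, spoVG averaged 11364 ± 4022 against 6806 ± 2531 RPKM (list adjusted p = 0.500). Of oxidative stress defence, sodA, for superoxide dismutase, averaged 4879 ± 1722 against 2893 ± 1284 RPKM (list adjusted p = 0.290). Of cell division and peptidoglycan synthesis, mraZ was 2.09-fold higher, and of secreted enzymes under the agr system the protease gene sspA was 1.80-fold higher (list adjusted p = 0.146 and 0.283). Nitrate and nitrite respiration had 6 of 7 members below 0 (adjusted p = 0.290), with a median of -0.69 relative to that of all genes between the replicate 2 libraries. Iron acquisition, osmoprotectant and prophage genes had 1, 3 and 0 members and were not tested.

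Abundant genes differed in the same way in separate pairs of libraries. Across the 114 genes with a mean of at least 1000 RPKM, the log2 difference between dormant and non-dormant replicate 1 was set against that of replicate 2, 2 pairs that share no library. Pearson's r across genes was 0.83 and Spearman's rho 0.75 (permutation test, adjusted p = 1e-05 for r, the smallest that 100000 permutations can give), and r was 0.80 without the 2 most extreme genes. Replicates 1 and 3 gave r = 0.85 and replicates 2 and 3 gave r = 0.74, with the same permutation p. Genes are not independent replicates, but the permutations shuffled values over genes as if they were. These p-values therefore measure no spread between libraries. The difference between non-dormant replicates 1 and 3, set against that between dormant replicates 2 and 3, gave r = 0.05. Lower in both pairs were ctsR, clpB and SERP0224, and higher in both were recA, arcB-2 and mqo-4.

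**Figure D4:**
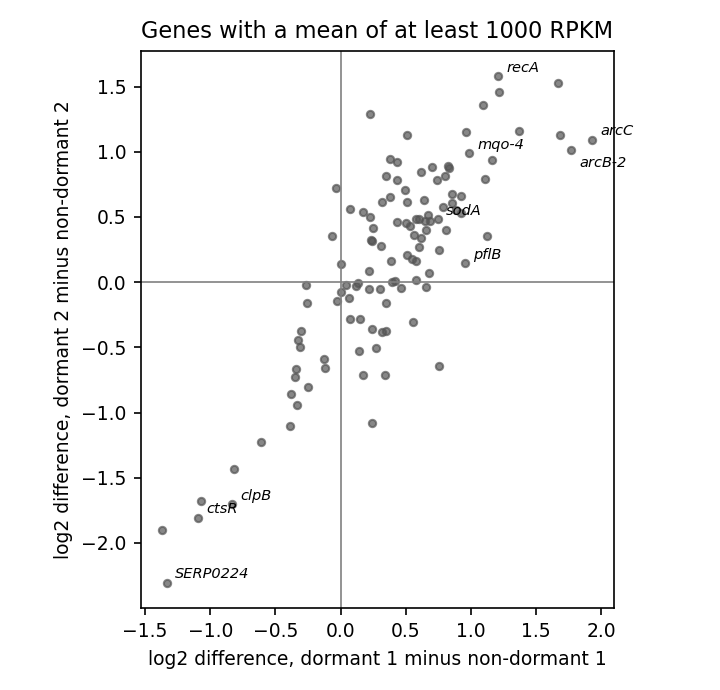
Log2 difference of RPKM + 1 between dormant and non-dormant replicate 1 (horizontal) and replicate 2 (vertical) for the 114 genes with a mean of at least 1000 RPKM. Each point is a gene, some are named, and Pearson's r across genes is 0.83.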

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

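Of the 341 transcripts not listed in all 6 files, 307 had more than 3 recovered reads in at least 1 library, which is above the limit that a count of 0 allows. Of the 341, 112 were listed for replicate number 1 only, with a median of 12 reads in the dormant and 8 in the non-dormant library. Another 181 were listed for numbers 1 and 3, with a median of 36 reads in dormant replicate 1, 24 in non-dormant replicate 1, 18 in non-dormant replicate 3 and 2 in dormant replicate 3. Their medians lay below the level of weak genes: 125 and 149 RPKM in dormant and non-dormant replicate 1 for the former, and 216, 242, 18.3 and 156 RPKM in dormant replicate 1, non-dormant replicate 1, dormant replicate 3 and non-dormant replicate 3 for the latter, against 283, 319, 19.2 and 203 RPKM for the 300 weak genes there. With transcripts listed for at least 2 replicate numbers included, 1912 in all and an alternative chosen after seeing the data, limma-trend still called 0 genes in either direction, with 75 higher and 14 lower at an unadjusted p below 0.05.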

How the results depend on the processing

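The counts of 0 genes higher and 0 lower were the same under median-of-ratios and upper-quartile scaling, the stricter filter, the smaller pseudocount, removal of rRNA genes and a 2-fold minimum. Among alternatives chosen after seeing the data, quantile normalization gave 7 higher and 10 lower, the background covariate 51 and 14, background subtraction 32 and 15 of 114 genes tested, and leaving out the 3 high-background libraries 352 and 56, while limma-voom on recovered reads called 0. Leaving out each library in turn gave 0 to 41 higher and 0 to 6 lower: 41 and 4 without dormant replicate 1, 5 and 6 without non-dormant replicate 1, and 0 without each other library. In those 2 fits, in the fit with the block and in that without the high-background libraries, limma pooled 1 common spread over all genes. With the replicate number as a block, 76 genes were higher and 17 lower. Same-numbered deviations from the group means correlated at 0.86, 0.73 and -0.53, and dormant 3 with non-dormant 2 at 0.68. The signs followed background, so pairing by number cannot be judged. The causes of these shifts were not tested apart from the test of background under the other observations.

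Of 6 lists past the set test, 0 held with an estimated correlation (camera, adjusted p from 0.340 to 0.794). With fry, which asks the different question of a change from 0, 0 passed (adjusted p from 0.425 to 0.473). Median-of-ratios scaling and limma-voom each gave 2 lists, the tricarboxylic acid cycle and purine biosynthesis, and background subtraction gave 1, chaperones. Upper-quartile scaling ended the calls of chaperones (adjusted p = 0.281), fermentation (0.0638) and the arginine and urease list (0.0581) and called purine biosynthesis (0.0316), and removal of rRNA genes ended that of the arginine and urease list (0.0541). Leaving out each library in turn gave 5 to 6 lists, and the block 4, without ribosomal proteins (0.0722) and the arginine and urease list (0.695). Without dormant replicate 1 and without non-dormant replicate 2, 3 of the 6 lists remained, the tricarboxylic acid cycle, fermentation and the respiratory chain, and glycolysis, oxidative stress defence and purine biosynthesis were called besides. The median log2 difference of all genes was -0.60 and -0.78 in these fits, against -0.17 in the main fit, so lists were set against other genes that had moved. Without non-dormant replicate 2, ribosomal proteins (adjusted p = 0.570), chaperones (0.823) and the arginine and urease list (0.998) turned direction relative to the other genes; ribosomal proteins also did with background subtraction (0.606), and fermentation did without the high-background libraries (0.991), with its own median still at 0.37. With each library left out in turn, adjusted p ranged from 3.10e-08 (without non-dormant replicate 1) to 0.871 (without dormant replicate 1) for ribosomal proteins, from 3.10e-08 to 0.823 for chaperones and from 0.000408 to 0.998 for the arginine and urease list. The tricarboxylic acid cycle passed in 16 of 18 alternatives and failed with the estimated correlation and fry. The 48 named genes kept their direction in all 832 refits over the alternatives, and 140 of these passed the threshold. They were chosen for small p in the same libraries, so a kept direction was largely set in advance and is no separate support. Passes came only with quantile normalization, the background covariate, background subtraction or a common spread pooled over all genes. Scaling moved the median log2 difference of all genes from -0.17 to -0.03 with median-of-ratios and to -0.22 with upper-quartile scaling. The shares of rRNA and of the 10 most abundant genes moved by less than the spread between libraries. Depth limits weak genes: 300 of the weakest had a median of 2 to 4 reads in the low-background libraries.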

Other observations

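Quantile normalization, an alternative chosen after seeing the data, gave every library the same distribution and called 17 genes, 8 with a symbol and 9 known by locus tag. Lower in dormant biofilms were ctsR, clpB and clpP, all of the Clp system of protein quality control, together with ald, for alanine dehydrogenase, and ppaC. Higher were recA, aldA-2, for an aldehyde dehydrogenase, and spoVG, for a regulator. On this scale the log2 difference was -1.69 ± 0.11 (SE) for ctsR (limma-trend, adjusted p = 0.00104), -1.25 ± 0.18 for clpB (0.0333) and 1.17 ± 0.17 for recA (0.0333). Each of these 8 genes was on the same side in 3 of 3 same-numbered pairs. The range over the alternatives was 1.15e-12 to 0.9999 in adjusted p for ctsR, 1.14e-11 to 0.9999 for clpB and 2.46e-13 to 0.9999 for recA. Of the 17 genes, 14 were also called with the background covariate and 15 with the replicate block; clpP was called with neither (0.227 and 0.522, against 0.0113 to 0.9999 over the alternatives), and spoVG was not with the covariate (0.317, against 0.00751 to 0.9999). Of the 10 splits of the 6 libraries into 3 and 3, the one that parts the high-background libraries gave 619 calls on this scale, and 8 gave 0.

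Stable RNAs took unequal shares of the libraries. The transcript whose identifier names tmRNA, which frees stalled ribosomes, took from 5.37% (95% Wilson interval 5.28% to 5.45%) of reads in dormant replicate 1 to 22.2% (22.0% to 22.4%) in non-dormant replicate 2. That of the signal recognition particle RNA took from 3.09% (3.02% to 3.15%) in dormant replicate 1 to 13.3% (13.2% to 13.5%) in dormant replicate 3. The group means were 10.3% ± 4.33 in dormant and 12.9% ± 8.17 in non-dormant libraries for tmRNA (exact permutation test, two-sided, p = 0.8), and 8.21% ± 5.12 and 5.76% ± 2.96 for the signal recognition particle RNA (exact permutation test, two-sided, p = 0.7).

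Of the tests below, those by gene order in another strain, of splits for the lists, and of repeatability were fixed before their result was seen; those by locus-tag number, read totals, dormancy, residual spread, splits for the genes and background corrections of the lists were chosen afterwards.

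The first pattern is the raised level of weak genes in dormant replicate 1, non-dormant replicate 1 and non-dormant replicate 3, where the 300 genes weakest in the other libraries had medians of 283, 319 and 203 RPKM, against 20.7, 19.2 and 13.6 RPKM in dormant replicates 2 and 3 and non-dormant replicate 2. The tables argue against dormancy as its source, since 2 of the 3 libraries are non-dormant and 1 is dormant, and against read totals, which were higher in the high-background library in 6 of 9 cross pairs. A candidate explanation is genomic DNA carried over despite the DNase step, because copies of a growing chromosome are more frequent near the replication origin. If locus-tag numbers follow gene order from the origin, distance from it can be counted from the nearer end of the numbering. Weak genes in the 3 libraries fell with that distance (median Spearman rho across 234 genes -0.46). Likewise 113 genes with symbols, from the weaker part of the transcripts in the other libraries, fell with gene order. That order was counted from dnaA in the nearer direction in strain ATCC 14990 (median rho -0.40). In the other libraries rho lay between 0.05 and 0.27 by tag number and between -0.06 and 0.05 by gene order, and other sources of even background remain open.

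The second pattern is the small number of genes past the threshold. Unequal background may account for much of it, but the test made cannot decide this. A covariate for background lowered the median residual SD of genes to 33.4% of its value, from 1.05 to 0.351 on the log2 scale. The covariate was taken from the same values, and the background difference was the first principal component, with 87.6% of the variance. Such a fall was therefore largely set in advance. The real split called 0 genes, so 10 of 10 splits gave at least as many by construction and that count decides nothing; 10 splits are also too few for a share under 0.05. The split that parts the high-background libraries gave 1157, the highest, which points to a structure of the samples other than the groups.

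The third pattern is the calls of 6 gene lists, since 2 of the 3 high-background libraries are non-dormant and unequal background could shift lists of weak genes; 2 corrections tested all members on all 6 libraries, and of the 6 lists 5 passed with the background covariate and 4 with quantile normalization, which also called purine biosynthesis (adjusted p = 0.0210), while the median log2 difference of all genes rose from -0.17 to 0.20 and 0.01. Of these calls 4 passed both, which cannot exclude background as their source. Quantile normalization did not remove its mark: the split that parts the high-background libraries still called 619 genes on that scale. Chaperones had camera adjusted p of 0.000283 and 7.63e-05, and up to 0.823 over all alternatives. Their list median was -0.29 (SD of members 0.52) before and -0.18 (0.62) and -0.44 (0.63) after. Ribosomal proteins had 3.44e-08 and 0.00764, and up to 0.871, with medians of -0.38 (0.55) before and -0.38 (0.50) and -0.34 (0.53) after. Under the covariate the chaperone median moved toward 0 and the ribosomal one stayed, so their lower adjusted p came with the rise of the other genes. The tricarboxylic acid cycle had 0.00290 and 0.00764, against 2.76e-06 to 0.525, with medians of 0.49 (0.47) before and 0.54 (0.40) and 0.29 (0.39) after. The respiratory chain had 0.0276 and 0.0321, against 8.24e-05 to 0.425, with medians of 0.68 (0.54) before and 0.55 (0.33) and 0.39 (0.44) after. The lead of these latter 2 over all genes shrank, so part of it may come from background. For the other 2 lists background cannot be told apart from the groups either. For fermentation both corrections ended the call (camera, adjusted p = 0.383 and 0.732, against a lowest of 8.24e-05 over the alternatives). Under the covariate this came because the other genes rose, as the list's own median was 0.38 (SD 0.41) before and 0.40 (0.43) after. With quantile normalization its median was 0.18 (0.49). For the arginine and urease list the covariate kept the call (0.00602, and up to 0.998 over the alternatives). Quantile normalization ended it (0.0829), with the median at -0.35 (0.94) before and -0.35 (0.87) and -0.40 (0.81) after. Comparisons within libraries of like background, that without the high-background libraries included, decide nothing, since each has a group of 1 library, and background subtraction tested only part of 3 lists. None of the 6 calls held with an estimated correlation, also under the covariate and quantile normalization, chaperones and ribosomal proteins failed without dormant replicate 1 (0.535 and 0.871) and without non-dormant replicate 2 (0.823 and 0.570), and the real split gave 6 lists and the highest other 10, with at least 6 in 8 of 10 splits, too few for a share under 0.05.

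A hypothesis fixed before its test was that abundant genes carry a difference between dormant and non-dormant libraries that recurs, with r above 0.3 between replicates 1 and 2 across genes. The value was 0.83. Other pairings that share no library gave 0.76 for dormant 1 minus non-dormant 3 against dormant 2 minus non-dormant 2, and 0.79 for it against dormant 3 minus non-dormant 2. Contrasts within a group gave 0.05 when both were within groups, and -0.34 for dormant 1 minus non-dormant 1 against dormant 2 minus dormant 3. These values are consistent with a difference of abundant transcripts between the groups, though any unrecorded handling that followed the groups would leave the same mark.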
